A study of Pimephales promelas with 16 samples.

How the data were processed

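The series holds gene expression arrays of liver from male fathead minnows (Pimephales promelas), a small freshwater fish used in toxicology. The labels give 2 groups of 8 biological replicates, a control group and a group held for 96 hours in EE2 at 25 ng/L. EE2 is the usual abbreviation of ethinylestradiol, a synthetic estrogen. Total RNA was extracted with Trizol and labelled with the green dye Cy3, per the labels' protocols, and each array carried the RNA of 1 sample. The 16 arrays lay on 2 slides with 4 control and 4 EE2 arrays each, read from the slide and position fields that accompany each scan. The first column of each slide held control arrays only. No replicate number is shared between the groups, so no pairing was used.

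The spot intensity values were made by the authors with Agilent Feature Extraction 10.7, per the submitters' processing notes, and the version in the file headers is 10.7.1.1. The deposited intensity used here as the main measurement is the processed signal, which per the file headers is background-subtracted within each array and not scaled between arrays. The deposited intensity files also hold the median brightness of each spot and of its local background, which were used for 1 alternative. Mean brightness had been intended for it and was not used here, because the columns given are medians. The series-wide table holds log2 values deposited by the authors. Its scaling steps are not given in the sources used here. Each of its columns had a rank correlation of 0.980 with the scanner values of its array. Every column had a median of 6.28, and the lowest value, 5.01, was shared by 20686 to 20830 spots per array, so a floor had been set. What that floor stood for and the software behind the table stay unknown. Every column of per-sample values was mapped to a sample.

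Control spots were left out, which left 61053 spots for 49849 probes. Of these probes, 41517 had 1 spot, 7973 had 2 spots and 359 had 10 spots. Spots marked as non-uniformity or population outliers, 0.420% of spots, were set to missing, and saturated spots were kept. The log2 processed signal minus the 75th percentile of each array was averaged over the spots of a probe. A probe was kept when it was well above background on at least 6 of the 16 arrays in any group, which 34029 probes (68.3%) met. Between 41.3% and 80.0% of probes were well above background on an array. The number of arrays limits the precision of every value.

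Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term), two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05, alone and with a fold of at least 2. Single values per array were compared with exact two-sided permutation tests over all 12870 splits of the arrays, for which the smallest possible p is 0.00016. Within 1 slide the smallest possible p is 0.029. These designs, the naming rule and the alternatives were fixed before the data were examined, except a few alternatives chosen after the data were seen and named as such. The check of calls from 1 slide on the arrays of the other and the counts at 4-fold and above under other scalings were also added after the data were seen. The naming rule took the probes with the largest rise and the largest fall among those past the threshold whose change had the same sign on both slides. The full rule took more genes in each direction and members of fixed gene lists, but the files do not pair the probe IDs with gene names. None of the probe IDs (0 of 49849) matched the 64593 genes of the reference gene table for assembly fPimPro1.hap1.1. The planned tests of genes, of gene lists, of vitellogenin and estrogen receptor genes and of cell type markers could therefore not be made, and 2 probe IDs are given in each direction.

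A probe that was well above background on no array of a group has only a rough level there. The fold of such a probe was taken as the mean of the bright group over the mean, in the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background on each array. Probes can go undetected above that lowest signal, so this fold is an estimate and not a strict lower bound. The named probes were above background on at least some arrays of each group, so this rule was not applied to them. Their fitted change is given with the number of such arrays where it was below 8.

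The steps were tested on simulated data with the means and spreads of 33514 probes with values on all arrays. Limma recovered 29 of 100 probes changed 2-fold and 85 of 100 probes changed 4-fold, with 5 false calls, and it called 0 probes when nothing was changed. In that simulation few probes were changed, which makes the adjustment stricter than in the real comparison. Alternatives covered background correction (normexp with an offset of 50), scaling, the filter on dim probes, slide and position, the variance model, outlier marks, the deposited log2 table, thresholds, a rank test and each array left out in turn.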

Results

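Liver RNA of 16 male fathead minnows was measured on 1-colour arrays, 8 from control fish and 8 from fish held for 96 hours in EE2 at 25 ng/L. The comparison asks which transcripts differ in male liver after exposure to this estrogen. The series title places the arrays in a comparison between laboratories, of which 1 laboratory's arrays are described here. The 75th percentile of the signal ranged from 514 to 1016 on control arrays and from 333 to 753 on EE2 arrays. Of 49849 probes, 18521 were well above background on all 16 arrays and 4294 on no array. The files do not pair the probe IDs with gene names, so probes are described by ID, size and direction of change.

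The livers of EE2-exposed fish differed from control livers over a large part of the array. Of 34029 probes tested, 8156 (24.0%) passed the threshold in limma, of which 4129 were higher and 4027 lower on EE2 arrays. At a fold of at least 2, 2080 probes rose and 1775 fell. At least 4-fold, 651 probes rose and 303 fell, and at least 16-fold, 129 rose and 18 fell. These splits rest on the scaling: on the E1A spike-ins, control transcripts added during labelling, 272 probes were higher and 2778 lower at 4-fold, and 76 and 80 at 16-fold. At least 100-fold, 34 probes rose and 0 fell, and 23 and 0 did on the spike-ins. Among 33514 probes with a value on every array, 1135 had every EE2 array above every control array and 646 had every EE2 array below every control array. Together these are 5.31% of the probes, where chance gives 0.0155%.

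The probe with the largest fitted rise was SINGLET_6610. Its normalised log2 signal was -2.76 ± 2.67 (SD, n = 8) in control fish and 7.02 ± 0.28 (SD, n = 8) in EE2 fish, a log2 change of 9.78 (SE 0.87, adjusted p = 6.4e-07 in limma, exact permutation p = 0.00016, higher in 8 of 8 EE2 fish than the control mean). SINGLET_432 rose by 9.66 on the log2 scale (SE 0.86), from -4.16 ± 2.605 to 5.50 ± 0.32 (SD, n = 8 each), with an adjusted p of 5.6e-07 in limma. Both probes were well above background on all 8 EE2 arrays, SINGLET_6610 on 5 and SINGLET_432 on 4 of the 8 control arrays. The size of these rises depends on the processing of the signal. With normexp background correction on median spot brightness, the log2 changes were 8.36 for SINGLET_6610 and 7.74 for SINGLET_432. In the deposited log2 table they were 9.41 and 8.52. Control 3 had the highest control level of both probes, and without it the log2 changes were 10.52 for SINGLET_6610 and 10.30 for SINGLET_432.

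The probe with the largest fitted fall was SINGLET_6261, at 4.04 ± 1.77 in control fish and -1.37 ± 1.62 in EE2 fish (SD, n = 8 each). It fell by 5.41 on the log2 scale (SE 0.78, adjusted p = 0.00013 in limma). UF_Ppr_AF_103721 fell by 5.40 (SE 1.17, adjusted p = 0.0030 in limma), from 2.73 ± 2.90 to -2.67 ± 2.11 (SD, n = 8 each). For both fallen probes, 8 of 8 EE2 fish lay below the control mean. Which of them fell further changed with the setting. UF_Ppr_AF_103721 was well above background on 5 of the 8 EE2 arrays. Its log2 change was -4.26 with normexp and -6.24 without control 14, which lay at -3.16, within the range of the EE2 arrays. On slide 2 alone its change of -5.13 did not pass the threshold (adjusted p = 0.12).

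**Figure D1:**
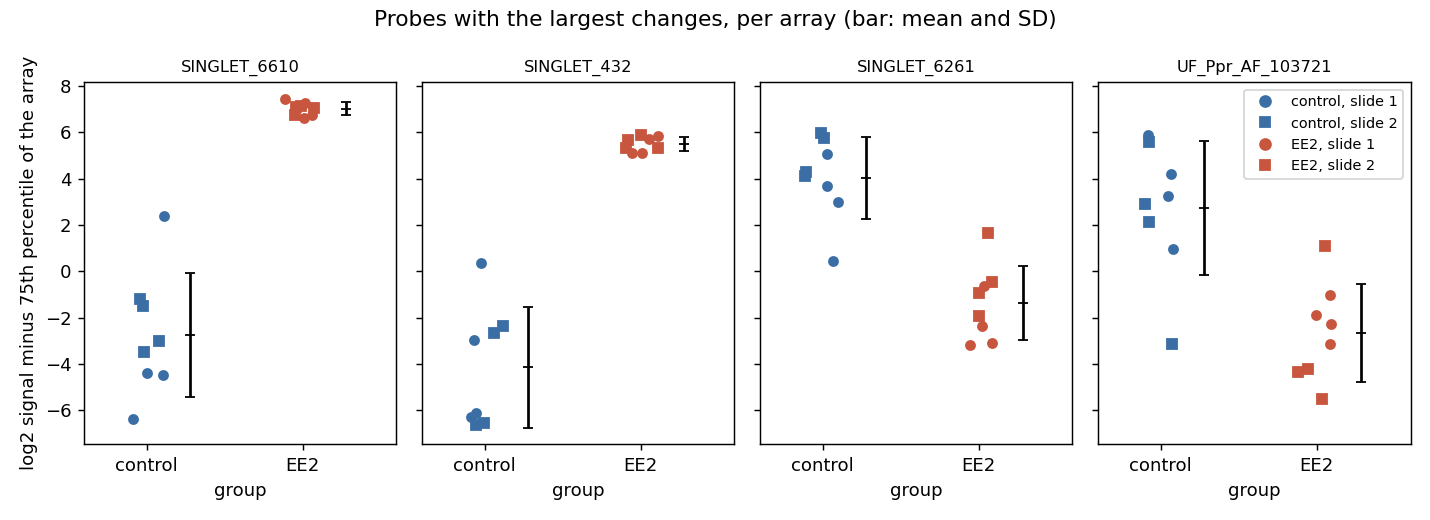
Normalised log2 signal (log2 signal minus the 75th percentile of the array, vertical axis) of the 4 named probes per array, with controls in blue, EE2 in red, circles for slide 1 and squares for slide 2; black marks give the mean and SD of 8 arrays. SINGLET_6610 lies between 6.63 and 7.45 on EE2 arrays and between -6.40 and 2.38 on control arrays.

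Some probes crossed the detection limit. On all 8 EE2 arrays and on none of the control arrays, 12 probes were well above background. Their rises were estimated at 16.5-fold in the median and 44.7-fold in the largest case. In the opposite direction, 14 probes were well above background on all 8 control arrays and on no EE2 array. Detection was judged on unscaled signal, which was lower on EE2 arrays, so loss of detection may partly follow array brightness. All 14 passed the threshold after scaling. Their median fall was estimated at 3.63-fold, and 13 of the 14 falls at 2-fold or more. These folds are not strict lower bounds, since probes can go undetected above the level used for the dim group.

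Both slides showed the change. With slide as a block, 8640 probes passed the threshold. Within slide 1, 1070 probes passed, and within slide 2, 4474 passed, each with 4 arrays per group. Of the 1070 probes called on slide 1 alone, 1054 (98.5%) changed in the same direction on the separate arrays of slide 2. Of the 4474 called on slide 2 alone, 4249 (95.0%) did so on slide 1. The counts by direction rest on scaling by the 75th percentile. Scaled on the E1A spike-ins, 664 probes were higher and 23846 lower on EE2 arrays, and the median change of all probes was -1.10 on the log2 scale. Without scaling, 809 were higher and 18341 lower, with a median change of -0.86. Changes are given here relative to that shift.

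The largest component of difference between arrays followed the treatment groups. The first principal component held 28.3% of the variance and separated the groups without overlap, with scores of -79.5 ± 14.6 in control and 79.5 ± 23.2 in EE2 (SD, n = 8 each, exact permutation p = 0.00016, the smallest possible, adjusted over 10 measures p = 0.00078). The difference was 148 within slide 1 and 170 within slide 2 (exact p = 0.029 in each, the smallest possible). The third component, with 9.56% of the variance, differed between slides by -70.7 (slide 2 minus slide 1, exact permutation p = 0.0022, adjusted p = 0.022) and not detectably between groups (exact p = 0.87).

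**Figure D2:**
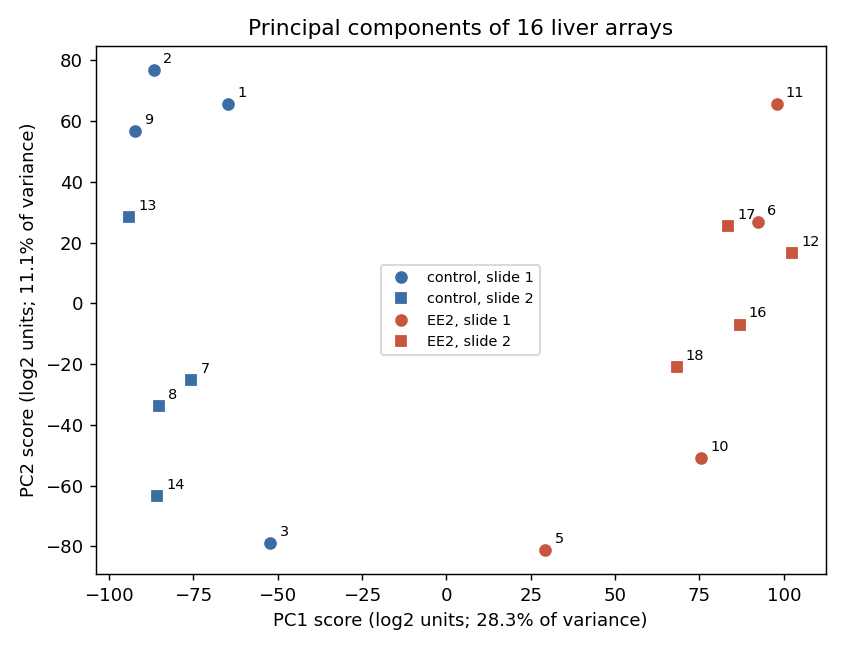
Scores of the 16 arrays on the first (horizontal) and second (vertical) principal components, in log2 units, labelled by replicate number, with controls in blue, EE2 in red, circles for slide 1 and squares for slide 2. Control arrays lie between -94.0 and -52.1 on the first component and EE2 arrays between 29.4 and 102.5.

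Pairs of arrays correlated, across probes, with a mean r of 0.933 within control (28 pairs), 0.941 within EE2 (28 pairs) and 0.902 between groups (64 pairs). Probes are not independent replicates, so no p is given. The highest of all 120 correlations, 0.958, joined 2 arrays of different groups, control 3 and EE2 5. The next highest between groups, 0.933, joined control 3 and EE2 10.

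**Figure D3:**
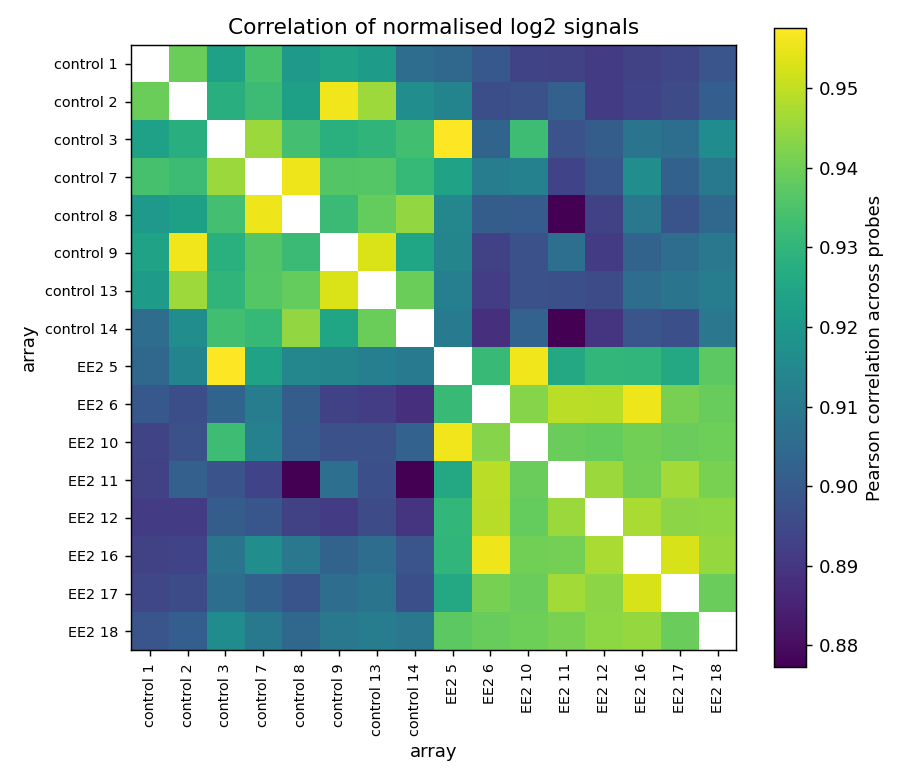
Pearson correlation across probes of the normalised log2 signals of each pair of arrays, with control arrays first and EE2 arrays after them on both axes; the colour scale gives r and the diagonal is blank. Pairs within a group reach 0.956, and the pair of control 3 and EE2 5 reaches 0.958.

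The overall signal of the sample probes was lower on EE2 arrays. The log2 75th percentile was 9.62 ± 0.33 in control and 8.78 ± 0.42 in EE2 (SD, n = 8 each), a difference of -0.84 (exact permutation p = 0.0016, adjusted p = 0.0039). It differed by -0.73 within slide 1 and -0.94 within slide 2 (exact p = 0.029 in each). The E1A spike-ins did not differ detectably, at 9.65 ± 0.23 and 9.88 ± 0.35 (SD, n = 8 each, exact permutation p = 0.15, adjusted p = 0.23). Within slide 1 they were higher on EE2 arrays by 0.44 (exact permutation p = 0.057), and within slide 2 by 0.022 (exact permutation p = 0.94). Relative to the spike-ins, the 75th percentile was lower by a log2 difference of -1.07 (exact permutation p = 0.00031, adjusted p = 0.0010), with -1.18 within slide 1 and -0.96 within slide 2 (exact p = 0.029 in each). The probes called at least 2-fold higher held 5.70% ± 0.45 of the summed signal on control arrays and 13.8% ± 1.15 on EE2 arrays (SD, n = 8 each).

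**Figure D4:**
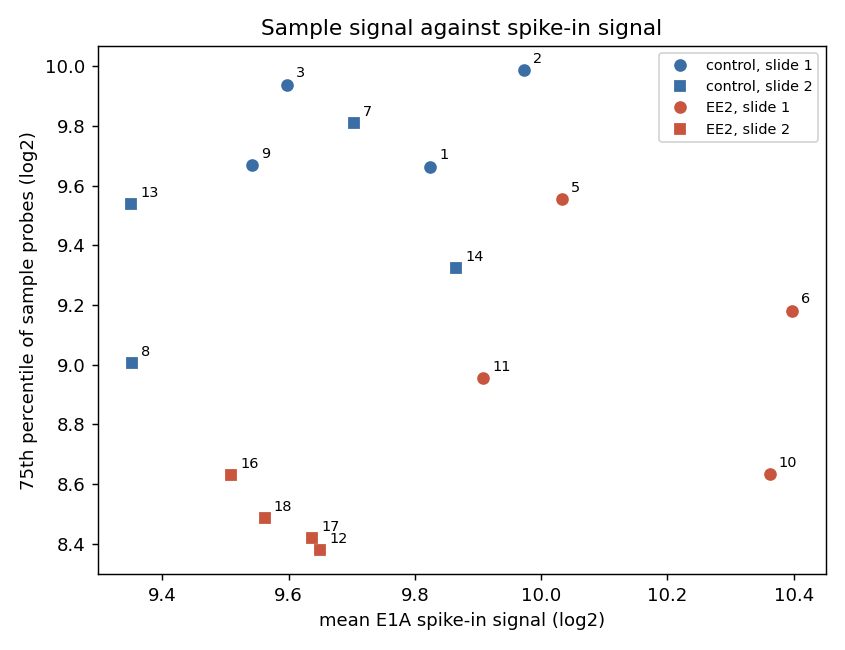
Log2 75th percentile of the sample probes (vertical) against the mean log2 signal of the E1A spike-ins (horizontal) for each array, labelled by replicate number, with controls in blue, EE2 in red, circles for slide 1 and squares for slide 2. Control arrays lie between 9.005 and 9.99 on the vertical axis and EE2 arrays between 8.38 and 9.56, with spike-in signals of 9.35 to 9.97 and 9.51 to 10.4.

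The spread between fish did not differ detectably between the groups over all probes. The median log2 ratio of the SDs, EE2 over control, was 0.016, and 82 of 100 permutations of the labels lay as far from 0. Among the 129 probes risen at least 16-fold, 108 had the larger SD in control (median 1.01, against 0.45 in EE2). Those probes were chosen by their rise in these data, so no test is given. They were dimmer on control arrays, with a mean log2 signal of -3.97 to -1.37 per array, against 2.14 to 2.99 on EE2 arrays. Control 3 lay 2.25 above the other controls in them, which adds to the control SD. Low signal and control 3 were not separated here from differences between fish. For 6068 probes with 2 spots, the median SD between spots of an array was 0.14, and the median SD between arrays of a group was 0.50, which holds labelling and hybridisation differences beside those between fish.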

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

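The tests of a slide difference, of the share of signal, of less labelled RNA, of carry-over, of a label swap, of mixing and of place on the slide were chosen only after the results were seen, except the subtraction of the carried share, which was set before its result.

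Arrays were compared with the rest of their group by the size of the gap to the nearest array, in 34 groups of values, where chance marks about 1 in 20. The marked values were 4. EE2 5 had a score of 29.4 on the first principal component, with the next EE2 array at 68.2. Over the 129 probes that rose at least 16-fold, with the control mean at 0 and the EE2 mean at 1, control 3 lay at 0.25 and the next control at -0.005, and EE2 11 lay at 1.09 with the next at 1.02. Over the 18 probes that fell at least 16-fold, control 3 lay at 0.66 and the next control at 0.11, and EE2 18 lay lower than control 3, at 0.64. Control 3 stood less apart over wider sets, at 0.16 over the probes that fell at least 4-fold, with control 14 at 0.11, and at 0.099 over those that rose at least 2-fold, with control 1 at 0.10.

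Control 3 stood above the other controls in the strongly risen probes by 2.25 on the log2 scale (SE 0.24 over probes). A swap with an EE2 sample is argued against, because the lowest EE2 array lay at 0.967 on the same scale. Carry-over of RNA from 1 EE2 sample was tested on probes that are on in the source. Apart from the source and control 3, they were on in at least 3 fish and off in at least 3, regardless of treatment. They were also kept only if control 3 lay well below the on level and the prediction well above the off level. The choice thus used the level under test, which limits how far above the prediction control 3 can lie. No probe was on in the source alone, so the sources can share probes. With EE2 5 as source and a carried share of 3.73%, control 3 lay -0.022 (SE 0.034, 6 probes) from the predicted level and 3.67 above other off arrays. As sources, EE2 18 (0.094, SE 0.42) and EE2 10 (0.39, SE 0.49) also gave levels within their SE of the prediction, on 6 probes each. Over the 6 of 8 sources with at least 5 probes the departures ran from -1.71 (EE2 17, SE 0.98) to 0.967 (EE2 12). A few percent of RNA from an EE2 sample is a candidate source of the raised levels, but the sample is not singled out. The probes are few, may share transcripts and were chosen partly by their level in control 3. No biological explanation was tested.

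Such carry-over cannot account for the fallen probes, where control 3 lay at -3.07 (SE 0.39) relative to the other controls and the carried share gives at most -0.060. Nor does it account for the resemblance of control 3 to EE2 5, whose correlation after removal of group means was 0.41, the highest of 120 pairs, and 0.385 after the carried share of EE2 5 was subtracted. Whether a shared column plays a part cannot be judged. The highest of 7 other pairs in 1 column of a slide reached 0.221 (SD 0.15). However, the pair had been picked as the highest of 120, so every other pair had to lie below it. Some of the 7 also lie within a group, where removal of group means lowers the correlation. Control 3 and EE2 5 also shared a slide, and the highest such correlation across slides was 0.137 (EE2 6 and control 7). EE2 10, on the same slide as both, had the next highest of all with control 3, at 0.275. With EE2 5 it reached 0.215, the highest within EE2. An effect of the shared slide stays open. Mixing in both directions stays open, as only 1 probe could show it in EE2 5, at 3.79 above other off arrays. Relatedness of the fish may also matter and was not tested.

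The lower signal of EE2 arrays against the spike-ins is not a slide difference, since it was -0.964 within the slide where it was smaller. Less labelled sample RNA stays open. The median fall differed by 0.094 between the dimmest and brightest of 4 groups of probes, called or not (SD between probes up to 0.96), but that spread is nearly as wide as the fall itself. The values weigh against a larger share taken by induced transcripts: the risen probes held 13.8% of the signal on EE2 arrays where 55.1% would be needed, a rise that lowers the rest by only -0.130. The 6 to 14 of them per EE2 array above 50% of the brightest signal held at most 3.38%, and 5 spots were saturated over all arrays. It stays open because compression of bright probes below saturation was not measured and summed signal was not converted to amounts of RNA. A true fall of transcripts per unit of total RNA would give a like fall at every brightness too and was not tested.

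For the number of changed probes, random splits of the arrays argue against chance, to no finer than 1 in 100. Only 1 of 100 splits, the real one, gave as many as 8156 probes, and the highest other gave 4389, in a split that kept 7 of the 8 EE2 arrays together. At 2-fold or more the real split gave 3855 probes, again 1 of 100, and the highest other gave 2410. The other splits mix EE2 and control arrays, which widens the spread within their parts and lowers their counts. Such splits do not test the place of the arrays on the slide.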

How the results depend on the processing

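Leaving out both control 3 and EE2 5 was chosen only after the data were seen, as were the median signal in normexp and the restriction of the spike-ins to 7 bright probes. The count of changed probes (8156) stayed within 1.5 times under quantile normalisation, median centring, slide as a block, slide with row, trend and robust variance, array weights, kept outlier spots, the deposited log2 table, the rank test, column as a covariate, no filter and both other filters on background. Without both control 3 and EE2 5 it was 8271. With 1 array left out it ranged from 7020 to 8684, with 3503 to 4525 higher and 3414 to 4159 lower, and at 2-fold from 3480 to 4364, with 1819 to 2415 higher and 1610 to 1949 lower. Scaling changed the split. Scaled on the spike-ins, 24510 probes changed (664 higher, 23846 lower), and at 2-fold 18980 (553 and 18427). Without scaling, 19150 changed (809 and 18341), and at 2-fold 13549 (675 and 12874). The shift of the whole array, kept by these settings, gives the fall. With normexp, 14102 changed (10216 higher), with 1053 lower at 2-fold, and with no filter 7170 were higher, 3930 of them 2-fold. The median log2 change of all tested probes was 0.198 with normexp and 0.178 with no filter, against -0.026 in the main setting. The extra higher probes came with this shift, whose cause was not tested. With fewer probes tested, well above background on all arrays, 2261 changed 2-fold (1243 and 1018). With fewer arrays, slide 1 gave 1070 (751 and 319), at 2-fold 1047 (737 and 310), and slide 2 gave 4474 (2279 and 2195). With column as a covariate, which overlaps with group, 5584 changed (3197 higher and 2387 lower). The total was near the edge of the 1.5 rule. The lower count, against 4027 in the main setting, was outside it. That setting kept 62.6% of the 8156 probes called in the main setting. At an adjusted p under 0.01, 4483 changed (2511 and 1972), and at 1.5-fold 7109 did (3708 and 3401). The named probes kept their direction under every setting that kept them and their side of the threshold, except UF_Ppr_AF_103721 on slide 2 (-5.13), but their size moved: SINGLET_6610 ranged from 8.36 to 10.55, SINGLET_432 from 7.74 to 10.36, SINGLET_6261 from -6.48 to -4.83 and UF_Ppr_AF_103721 from -6.47 to -4.26 over the settings with no single array left out. The first component, the spike-ins and the 75th percentile over them kept direction and side of the threshold under the 2 alternatives run for each. The SD ratio, never past the threshold, ranged from -0.036 to 0.059 with 1 array left out. It was below 0 without EE2 5 (-0.036), EE2 11 (-0.00032) and EE2 18 (-0.029). Dim signal limits the fold of probes near background. Gene, gene list, vitellogenin and marker alternatives were not run because probes have no gene names here.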

Other observations

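The test of consecutive probe numbers was chosen only after the result was seen.

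Some probes were on in some fish and off in others whatever the treatment. Among probes not called between groups, 48 had a gap of at least 4 log2 units with at least 3 arrays on each side and both states in each group. Values drawn from normal distributions with the same means and SDs gave 4 such probes, which argues against a wide spread between fish without separate states. The 48 probes made 33 distinct patterns over the arrays, and the median pair of arrays shared the state of 54.2% of them. Control 3, EE2 5 and EE2 10 shared the most, with 93.8% for control 3 and EE2 10, 93.8% for EE2 5 and EE2 10, and 91.7% for control 3 and EE2 5. Inherited differences between fish may underlie such probes, which these data did not test.

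Probes with consecutive SINGLET numbers changed alike more often than chance. Both members rose at least 4-fold in 16 of 7566 consecutive pairs, against a mean of 3.04 and a highest of 11 in 10000 shuffled numberings. Consecutive numbers may measure 1 transcript more often than random pairs, so counts of probes should not be read as counts of genes.

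Of 43 other control probes not used elsewhere, 1 differed between groups, ERCC-00012_90, chosen after its values were seen. Its mean log2 signal was 6.21 in control and 4.43 in EE2 (exact permutation p = 0.00078, adjusted p = 0.033), and it was well above background on 9 of 16 arrays.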
